A study of Mus musculus with 7 samples.

How the data were processed

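RNA was measured by bulk sequencing of ovaries from mice aged 8 to 12 weeks. The 7 libraries fell into 3 groups by their titles. These were wild type mice on the CD diet (2 libraries, fertile), Abcg5/Abcg8 knockout mice on the CD diet (3 libraries, infertile) and knockout mice on the VOFD diet (2 libraries, fertile). The full names of both diets are not given in the sources used here. Each ovary was homogenised by itself, per the labels' protocols. Separate animals per library are not stated, so p-values measure the spread between these samples, which may be partly technical.

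The values are TPM, a length-scaled share of transcripts per gene, as deposited by the authors for 34866 genes together. Each column summed to 1000000, so TPM keeps no sequencing depth and no counting interval or detection floor was computed. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. Genes that share sequence with a copy, and genes that overlap an antisense partner, therefore cannot be separated with certainty.

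Gene identifiers were versioned Ensembl IDs, of which 34582 were matched to a symbol and 284 were not. Coordinates were taken from GENCODE M21, an annotation of GRCm38, which held 34652 of the IDs when the version was ignored and 32644 with the same version. By that annotation 21850 were protein coding genes and 12300 were pseudogenes.

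Values were transformed as log2(TPM + 1), and genes with a TPM of at least 1 in at least 2 libraries were kept, which left 15487. All fold changes are on that scale, which understates changes of low genes. Linear models were fitted with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8), an intensity trend in the variance prior and 2-sided tests. All 7 libraries entered 1 fit with 3 group means (4 residual degrees of freedom). Infertile against fertile was fitted with 2 group means (5 residual degrees of freedom), which pools wild type CD and knockout VOFD libraries. P-values were adjusted over the 15487 genes by Benjamini and Hochberg (BH), with a threshold of 0.05. Group values are means ± SD of TPM.

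The tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Named genes passed the threshold, had groups that did not overlap and had a mean of at least 5 TPM in the higher group, with up to 10 taken per direction by fold change. Unnamed gene models, pseudogenes, small RNA genes, immunoglobulin and T cell receptor segments and ribosomal protein genes were left out. Where fewer than 10 passed, genes with the smallest unadjusted p filled the number up to 10 and are given as not past the threshold. From each list, up to 4 members with the smallest p in a comparison could be named, called or not. Any other gene named below was chosen after its values were seen.

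The 29 fixed gene lists covered the targeted genes, granulosa cell markers, corpus luteum and luteinisation, theca and interstitial cell markers, oocyte genes, ovulation and cumulus expansion genes, steroidogenesis, cholesterol biosynthesis, LXR target genes, lipid storage and uptake, macrophages, lymphocytes, neutrophils and mast cells, inflammatory cytokines, interferon-stimulated genes, extracellular matrix, endothelium, smooth muscle and pericytes, ovarian surface epithelium, oviduct epithelium, adipose tissue, erythroid blood cells, the unfolded protein response and ATF4, apoptosis and follicle atresia, cell proliferation, immediate early genes, mitochondrially encoded genes, oxidative stress response, and gonadotropin, prolactin and oestrogen receptors and signalling. Lists with at least 3 tested members were tested, which left 28, since neither targeted gene passed the filter. Some genes stand in 2 lists, such as Lipe and Fabp4.

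Each list was set against all other tested genes with limma's camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, and BH over the 28 lists. The direction camera gives is relative to the other genes, so it can differ in sign from a list's median where the median of all genes was not 0. The fry test, which asks whether the genes of a set move on balance one way and compares the set with no other genes, was run beside it. Its mixed form, which asks whether members change in either direction, was computed with it. Members past the threshold were counted over all genes tested and adjusted over the list alone.

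The models were tested on simulated data built from the means and spreads of these libraries, with 200 of 15487 genes changed in each of 5 simulations. For knockout CD against wild type CD, 28.4% of changes of 1 on the log2 scale, 82.7% of changes of 2 and 97.3% of changes of 4 were recovered, with 7 false calls on average. For knockout VOFD against knockout CD the shares were 28.1%, 84.8% and 98.2% with 8 false calls on average. For knockout VOFD against wild type CD they were 20.0%, 77.9% and 94.2% with 6.8 false calls, and for infertile against fertile 53.1%, 91.0% and 99.7% with 8.4. In each comparison 5 of 5 shifted lists were recovered, and of 200 unchanged lists 0 were called, except 2 in knockout VOFD against wild type CD. Changed genes and list members had a mean log2(TPM + 1) above 2, so the recovery of lower genes was not measured. Each gene had the same spread in all libraries, although the knockout CD libraries stood farther apart. These rates therefore need not hold for the real data. Noise was drawn independently for each gene and the simulated lists were random. The false calls therefore say nothing of lists whose members move together. In knockout CD against wild type CD the estimated correlation was 0.97 for erythroid and 0.57 for cholesterol genes.

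Alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalisation, no variance trend, other samples in the fit, the replicate number as a block, and each library left out in turn. Library quality weights and a crossed numbering of replicates were added after the data were seen. Pseudogene transcripts were compared with protein coding transcripts of the same annotation by blastn 2.17.0+. No column of the table was left unused.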

Results

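The ovarian transcriptome was compared between wild type mice, mice that lack the sterol transporter genes Abcg5 and Abcg8, and such knockout mice on a second diet. ABCG5 and ABCG8 form a half-transporter pair that exports cholesterol and plant sterols from cells. The libraries comprised 2 from fertile wild type mice on the CD diet, 3 from infertile knockout mice on the CD diet and 2 from fertile knockout mice on the VOFD diet. The depth of the libraries is unknown, since the values were TPM. Between 14267 and 14982 genes reached 1 TPM in a library.

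Abcg8 (ENSMUSG00000024254.15, GRCm38 chromosome 17, 84676302 to 84700333) and Abcg5 (ENSMUSG00000040505.13, chromosome 17, 84658234 to 84683011) were near 0 in all 7 libraries. Abcg8 was at 0.073 and 0.0423 TPM in wild type CD, at 0.0486, 0.0554 and 0.157 TPM in knockout CD, and listed at 0 in both knockout VOFD libraries. Abcg5 was at 0.0767 and 0.149 TPM in wild type CD, at 0.0360, 0.0268 and 0.128 TPM in knockout CD, and at 0.156 and 0.212 TPM in knockout VOFD. Neither gene was tested, and their levels were too low to check the genotype labels.

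Knockout CD libraries stood farther apart from each other than the wild type CD or knockout VOFD libraries did. The first principal component held 39.7% of the variance and placed knockout CD library 3 at 65.5, knockout CD library 2 at 19.6 and knockout CD library 1 at -7.21, while the 4 fertile libraries lay between -29.7 and -15.1. The second held 18.8% and placed knockout CD library 1 at -45.1. In that library the theca enzyme gene Cyp17a1 was at 3.53 TPM, against 150 and 81.9 TPM in the other knockout CD libraries, and Adamts1, a protease gene of ovulation, was at 79.3 TPM against 10.1 and 11.4 TPM. Mitochondrially encoded transcripts made up 17.3%, 15.4% and 11.7% of TPM in knockout CD libraries 1, 2 and 3. Globin transcripts made up 0.220%, 0.304% and 0.126% in the same libraries, and between 0.0439% and 0.0833% in the fertile ones.

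In knockout CD ovaries Ptgfr and Akr1c18, both expressed by luteal cells, fell, and the genes with the greatest rise were pseudogenes. Ptgfr, the prostaglandin F receptor gene of luteal cells (ENSMUSG00000028036.6, chromosome 3, 151796502 to 151837630), fell to 4.17 ± 1.73 TPM (SD, n = 3) from 194 ± 91.8 TPM (n = 2), a log2 fold change of -5.20 (SE 0.36, limma BH adjusted p = 0.00108). Akr1c18, which encodes the enzyme that inactivates progesterone (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654), fell to 3.65 ± 3.59 TPM from 202 ± 51.9 TPM (log2 fold change -5.68, SE 0.69, adjusted p = 0.0306). The endothelial lipase gene Lipg (ENSMUSG00000053846.4, chromosome 18, 74939322 to 74961263) fell to 2.81 ± 0.886 TPM from 65.0 ± 41.8 TPM (log2 fold change -3.98, SE 0.48, adjusted p = 0.0306). Cox8b, a subunit gene of cytochrome c oxidase known from muscle and brown fat, rose to 20.2 ± 4.48 TPM from 1.57 ± 1.59 TPM (log2 fold change 3.18, SE 0.38, adjusted p = 0.0306).

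The other named genes that fell were Tnfrsf9, a receptor gene of the tumour necrosis factor family (log2 fold change -3.59, adjusted p = 0.0168), the lens crystallin gene Cryba4 (-3.14, adjusted p = 0.0359), Ramp1, a receptor activity modifying protein gene (-2.79, adjusted p = 0.0110), and S100a4 (-2.26, adjusted p = 0.0312). Saa2, an acute phase gene, fell as well (-4.35, adjusted p = 0.0295). Its values were 1.06, 0 and 0 TPM in knockout CD and 19.2 and 32.1 TPM in wild type CD. Srd5a1, the steroid 5-alpha reductase gene, was at 46.8 ± 1.70 TPM against 17.3 ± 0.467 TPM and missed the threshold (adjusted p = 0.0503). In total 17 genes passed, 9 higher and 8 lower, and 1599 had an unadjusted p under 0.05 where chance gives 774. With median-of-ratios scaling the count was 19, with 7 higher and 12 lower. Of the 9 higher genes, 7 were pseudogenes, given with their best matching genes further on, and 1 was the immunoglobulin constant gene Iglc1.

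The calls depended on the libraries. The count was 7 without wild type CD library 1, 4 without wild type CD library 2, 174 (105 higher and 69 lower) without knockout CD library 1 and 7 without knockout CD library 2. Of the 9 named genes, 6 lost their call without wild type CD library 1, 8 without wild type CD library 2, 7 without knockout CD library 2 and 4 without knockout CD library 3, with adjusted p between 0.0571 and 0.567. Ptgfr kept its call in each of these fits. Akr1c18 lost it without wild type CD library 1 (0.265) or 2 (0.506) and knockout CD library 2 (0.149) or 3 (0.0804).

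Of 24 tested cholesterol biosynthesis genes, 21 had a negative fold change in knockout CD against wild type CD with a median of -0.60, 0 fell over all genes tested and 9 fell when adjusted over the list alone. Msmo1, a sterol methyl oxidase gene, was at 60.3 ± 11.1 TPM against 144 ± 25.9 TPM (adjusted p = 0.119), and Idi1, the isopentenyl diphosphate isomerase gene, was at 16.3 ± 4.78 TPM against 51.6 ± 18.2 TPM (adjusted p = 0.131). Camera gave an adjusted p of 1.93e-17 for the list, and adjusted p = 0.473 with an estimated correlation. The corpus luteum and luteinisation list had a median of -0.73 over 17 members, of which 2 fell over all genes tested and 5 adjusted over the list alone (camera adjusted p = 6.40e-11, adjusted p = 0.473 with an estimated correlation). Sfrp4, a secreted Wnt antagonist gene of luteal cells, was at 37.3 ± 30.2 TPM against 795 ± 386 TPM (adjusted p = 0.131), and Lhcgr, the luteinising hormone receptor gene, at 36.3 ± 17.8 TPM against 134 ± 52.0 TPM (adjusted p = 0.242). Without knockout CD library 1 the luteal list had 8 members lower over all genes tested and 10 adjusted over the list alone. Without wild type CD library 2 the cholesterol list had 0 and the luteal list 3 adjusted over the list alone, and without knockout CD library 2 the cholesterol list had 5. The luteal median was -1.18 without wild type CD library 1 and -1.27 without knockout CD library 1, and the cholesterol median -0.32 without wild type CD library 2.

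In the same comparison the adipose tissue list had a median of 2.02 with 10 of 11 members positive, 0 past the threshold over all genes tested and 9 adjusted over the list alone (camera adjusted p = 4.95e-07, adjusted p = 0.473 with an estimated correlation). Its members included Cfd at 674 ± 302 TPM against 125 ± 84.4 TPM (adjusted p = 0.207) and Fabp4 at 913 ± 426 TPM against 160 ± 121 TPM (adjusted p = 0.214). The erythroid list had a median of 1.71 with 5 of 5 positive, 0 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 2.82e-06, adjusted p = 0.473 with an estimated correlation), and Hba-a1 was at 288 ± 102 TPM against 81.8 ± 35 TPM (adjusted p = 0.139). Without wild type CD library 2 the adipose list had 0 members and the erythroid list 3 adjusted over the list alone.

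LXR target genes, which promote sterol export and fatty acid synthesis, had a median of 0.38 with 14 of 17 positive. Of these 0 passed over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0271, adjusted p = 0.473 with an estimated correlation). Abca1, a sterol exporter gene, was at 69.0 ± 22.9 TPM against 21.9 ± 4.76 TPM (adjusted p = 0.140), and Fasn, the fatty acid synthase gene, at 177 ± 52.1 TPM against 51.5 ± 13.7 TPM (adjusted p = 0.140). Lipid storage and uptake genes had a median of 0.43, 0 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0400, adjusted p = 0.473 with an estimated correlation). Both lists lost their camera call without wild type CD library 2 (adjusted p = 0.185 and 0.440) and without knockout CD library 1 (0.0893 and 0.358), and the lipid list also without knockout CD library 2 (0.0785). Adjusted over the list alone, the LXR count was 2 with median-of-ratios scaling and 3 with quantile normalisation, 1 without wild type CD library 2, 2 without knockout CD library 2 and 3 without wild type CD library 1 or knockout CD library 3. The LXR median was 0.17 with median-of-ratios scaling and 0.19 without knockout CD library 3. With median-of-ratios scaling the lipid median was 0.22 with a count of 3 and the call was lost (0.0638), and with quantile normalisation the count was 2. Lipid and adipose scores were both highest in knockout CD library 1 (5.97 and 7.14) and lowest in wild type CD library 2 (5.10 and 3.91). Both lists hold Fabp4, so lipid genes of ovarian cells cannot be told from those of adipose tissue here. The lipid count was 0 without wild type CD library 2 and 4 without knockout CD library 2, knockout VOFD library 1 or knockout VOFD library 2.

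Cell proliferation genes were positive in 19 of 19 members with a median of 0.53, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 9.63e-04, adjusted p = 0.678 with an estimated correlation; 0.0546 without knockout CD library 2). Macrophage genes had a median of 0.54 with 17 of 19 positive (camera adjusted p = 0.0111, adjusted p = 0.678 with an estimated correlation; 0.0785 without knockout CD library 2). Neutrophil and mast cell genes had a median of 0.85 with 9 of 9 positive (camera adjusted p = 0.0138, adjusted p = 0.649 with an estimated correlation). Lymphocyte genes had a median of 0.48 with 11 of 11 positive (camera adjusted p = 0.0400, adjusted p = 0.649 with an estimated correlation). None of the macrophage or neutrophil genes and 2 of the lymphocyte genes passed when adjusted over the list alone, and 0 passed over all genes by limma. The neutrophil and lymphocyte calls were lost without wild type CD library 2 (0.319 and 0.371) and without knockout CD library 2 (0.584 and 0.164). Without knockout CD library 1, 15 proliferation, 10 macrophage and 4 neutrophil genes rose when adjusted over the list alone, and 4 neutrophil genes did without knockout CD library 3. The lymphocyte count was 0 without wild type CD library 1, wild type CD library 2 or knockout CD library 2, and 1 without knockout CD library 3. Without knockout CD library 3 the medians were 0.28 for proliferation and 0.29 for macrophages, and without knockout CD library 2 that for neutrophils was 0.52. With median-of-ratios scaling the proliferation median was 0.32 and the macrophage median 0.34.

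Among lists below the other genes, oocyte genes had a median of -0.17 (camera adjusted p = 8.61e-05, adjusted p = 0.684 with an estimated correlation), and camera gave the opposite direction with an adjusted p of 0.796 without knockout CD library 1. Their median was 0.23 without that library, -0.51 without knockout CD library 2, -0.30 without wild type CD library 1 and -0.03 without wild type CD library 2. Steroidogenesis genes had a median of -0.12 (camera adjusted p = 0.0332, adjusted p = 0.473 with an estimated correlation), with 1 member lower over all genes, and 3 lower and 2 higher adjusted over the list alone. This call was lost without wild type CD library 1 (0.0771), knockout CD library 2 (0.106) or knockout CD library 3 (0.109), with median-of-ratios scaling (0.214) and with the replicate number as a block (0.0799). The median was -0.08 without wild type CD library 2 and -0.17 without knockout CD library 1. Adjusted over the list alone it had 6 lower and 4 higher members without knockout CD library 1, and 1 lower and 2 higher without wild type CD library 2. Mitochondrially encoded genes were negative in 13 of 13 with a median of -0.19 (camera adjusted p = 2.24e-05, adjusted p = 0.649 with an estimated correlation; 0.109 without knockout CD library 3, 0.137 with the replicate block). Their median was -0.12 without wild type CD library 2, -0.35 without knockout CD library 1 and -0.05 without knockout CD library 3. The median fold change of all genes was 0.19. Of 28 lists, 16 passed camera with the preset correlation, 8 higher and 8 lower. With an estimated correlation 0 passed and 1 had an unadjusted p under 0.05, and by directional fry 0 passed and 4 had one. By mixed fry the steroidogenesis (adjusted p = 0.00169), luteal (0.00279), lipid storage (0.00888), LXR (0.0138) and oxidative stress lists (0.0197) passed. The cholesterol (0.0701) and adipose lists (0.0955) were among those that did not.

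Ptgfr and Akr1c18 went the other way with the change of diet within the knockout. Ptgfr rose to 163 ± 43.0 TPM (n = 2) in knockout VOFD from 4.17 ± 1.73 TPM (n = 3) in knockout CD (log2 fold change 5.01, SE 0.36, limma BH adjusted p = 0.00292). Akr1c18 rose to 362 ± 331 TPM from 3.65 ± 3.59 TPM (log2 fold change 6.16, SE 0.69, adjusted p = 0.0323). Tnfrsf9 rose to 16.1 ± 3.66 TPM from 0.549 ± 0.311 TPM (3.47, adjusted p = 0.0262), and Ramp1 to 25.5 ± 5.36 TPM from 3.77 ± 1.03 TPM (2.48, adjusted p = 0.0262). Genes close to the threshold were Lipg at 56.1 ± 34.1 TPM against 2.81 ± 0.886 TPM (adjusted p = 0.0694), and Msmo1, S100a4, the prostaglandin D synthase gene Ptgds, the stem cell marker gene Lgr5 and Saa2, each with an adjusted p of 0.0900.

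In total 7 genes passed, 6 higher and 1 lower, and 1230 had an unadjusted p under 0.05. The higher genes outside the naming rule were the pseudogene Gm16232 and the immunoglobulin segment Ighv1-62-1, both listed at 0 in all 3 knockout CD libraries. Gm16232 was at 7.14 and 6.57 TPM and Ighv1-62-1 at 3.89 and 4.84 TPM in knockout VOFD. The count was 4 without wild type CD library 1, 4 without wild type CD library 2, 104 without knockout CD library 1 (51 higher and 53 lower), 3 without knockout CD library 2, 3 without knockout VOFD library 1 and 4 without knockout VOFD library 2. Ptgfr kept its call in each of the 7 fits that left out 1 library. Wild type CD libraries enter this comparison through the shared spread only. Without either of them the log2 fold changes of Akr1c18 and Ramp1 stayed at 6.16 and 2.48. Akr1c18 lost its call without wild type CD library 1 (0.107), wild type CD library 2 (0.107), knockout CD library 2 (0.169), knockout CD library 3 (0.105) and knockout VOFD library 2 (0.0879). Tnfrsf9 lost its call without knockout CD library 2 (0.102) or 3 (0.0723) and knockout VOFD library 1 (0.315) or 2 (0.0959), and Ramp1 without wild type CD library 1 (0.0775) or 2 (0.0787), knockout CD library 2 (0.116) and knockout VOFD library 1 (0.157) or 2 (0.239).

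Cholesterol biosynthesis genes had a median of 0.84 in knockout VOFD against knockout CD, with 22 of 24 members positive. None passed over all genes tested by limma and 14 rose when adjusted over the list alone (camera adjusted p = 2.19e-21, adjusted p = 0.682 with an estimated correlation). Msmo1 was at 168 ± 17.5 TPM against 60.3 ± 11.1 TPM, and Sc5d, the sterol C5 desaturase gene, at 82.9 ± 6.49 TPM against 37.2 ± 3.30 TPM (adjusted p = 0.128). The corpus luteum and luteinisation list had a median of 0.66, with 2 members higher over all genes and 4 adjusted over the list alone (camera adjusted p = 3.15e-08, adjusted p = 0.682 with an estimated correlation). Sfrp4 was at 577 ± 148 TPM against 37.3 ± 30.2 TPM (adjusted p = 0.227). The cholesterol count adjusted over the list alone was 6 without knockout CD library 2 and 4 without knockout VOFD library 1, and the luteal count was 10 without knockout CD library 1. The luteal median was 1.05 without knockout CD library 1 and 0.37 without knockout CD library 2.

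Erythroid genes were negative in 5 of 5 members with a median of -1.57, 0 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.690 with an estimated correlation). The adipose list had a median of -1.07 with 0 past either threshold (camera adjusted p = 0.00263, adjusted p = 0.710 with an estimated correlation; 0.244 without knockout CD library 1 and 0.506 without knockout VOFD library 1). Adipose genes adjusted over the list alone numbered 5 without knockout VOFD library 2. The adipose median was -0.64 without knockout CD library 1, -0.38 without knockout VOFD library 1 and -1.70 without knockout VOFD library 2. Proliferation genes were negative in 19 of 19 with a median of -0.50 (camera adjusted p = 1.00e-05, adjusted p = 0.697 with an estimated correlation), with 0 past over all genes and 2 adjusted over the list alone. The count of 2 was 16 without knockout CD library 1 and 0 without each of the other 6 libraries. Neutrophil and mast cell genes were negative in 9 of 9 with a median of -1.28 (camera adjusted p = 6.66e-05, adjusted p = 0.697 with an estimated correlation; 0.0511 without knockout CD library 2, with a median of -0.81). Oocyte genes were positive in 32 of 33 with a median of 0.50 and 0 past either threshold (camera adjusted p = 1.76e-10, adjusted p = 0.697 with an estimated correlation). Their median was 0.15 without knockout CD library 1 (camera adjusted p = 0.00167) and 0.81 without knockout CD library 2, where 1 rose adjusted over the list alone. The oocyte score was 3.99 in knockout CD library 1 and 5.28 in knockout CD library 2, against 5.18 and 5.15 in knockout VOFD. LXR target genes had a median of -0.03 (camera adjusted p = 0.812). Of 28 lists, 12 passed camera with the preset correlation, 5 higher and 7 lower. With an estimated correlation 0 passed and 2 had an unadjusted p under 0.05, and by directional fry 0 passed and 4 had one. By mixed fry the luteal (adjusted p = 0.00348) and steroidogenesis lists (0.014) passed, and the cholesterol list (0.0621) did not.

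Of the 17 genes that differed between knockout CD and wild type CD, 5 differed in the opposite direction between knockout VOFD and knockout CD. Ptgfr, Akr1c18, Tnfrsf9 and Ramp1 were lower in knockout CD than in either fertile group, and the pseudogene Gm12191 was higher. Over independent lists 0.00310 genes lower then higher and 0.000581 higher then lower would be shared. Both comparisons share the 3 knockout CD libraries, and 50 simulations of unchanged groups that share them gave 0 such genes. With no gene changed, hardly any passes the BH threshold in either comparison. The 0 was thus nearly fixed in advance and says nothing of the 5. Each simulated gene also had the same spread in all libraries. At an unadjusted p under 0.05 there were 687 such genes, against a simulated mean of 173.6 and a highest simulated value of 203. Noise was drawn independently for each simulated gene, so the simulated counts vary less than those of genes that move together. How far 687 lies beyond chance is therefore not known. The 3 knockout CD libraries could not be split into parts of at least 2 libraries, so the share of the excess that comes from the shared libraries is not known. Without wild type CD library 1 the count of 5 was 3, without wild type CD library 2 or knockout CD library 2 it was 2, without knockout VOFD library 1 or 2 it was 3, and without knockout CD library 1 it was 80.

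The fertile groups, knockout VOFD and wild type CD, differed in genotype and diet together. Both genes past the threshold were pseudogenes, Gm45315 (chromosome 7, 12797529 to 12797861) and Gm6969 (chromosome 12, 24638669 to 24639010), both higher, and 308 genes had an unadjusted p under 0.05 where chance gives 774. The lower number is no sign that the groups were alike, since the shared spread includes the knockout CD libraries, which stood farther apart. Fitted by limma without them, 21 genes passed and 817 had an unadjusted p under 0.05. Hmgb1, a chromatin protein gene, was at 263 ± 42.7 TPM against 597 ± 0.931 TPM (adjusted p = 0.370), and Tdg, a DNA glycosylase gene, at 7.47 ± 0.320 TPM against 22.3 ± 3.72 TPM (adjusted p = 0.550). Acss2, an acetyl-CoA synthetase gene, was at 22.6 ± 6.82 TPM against 8.93 ± 0.571 TPM (adjusted p = 0.902). Ptgfr was at 163 ± 43.0 TPM against 194 ± 91.8 TPM in these groups. The count of 2 was 6 without knockout CD library 1 and 14 without knockout CD library 3, which enter this comparison through the shared spread only.

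Immediate early genes, which respond within minutes to stimuli, were negative in 14 of 14 members with a median of -0.55 in knockout VOFD against wild type CD. Over all genes 0 passed by limma and 1 adjusted over the list alone (camera adjusted p = 3.89e-18, adjusted p = 0.184 with an estimated correlation). The count of 1 was 4 without knockout CD library 3 and 0 without either wild type CD or either knockout VOFD library. Nr4a1, an orphan nuclear receptor gene, was at 9.26 ± 2.02 TPM against 23.6 ± 1.1 TPM. LXR target genes were positive in 17 of 17 with a median of 0.39 and 0 past either threshold (camera adjusted p = 2.20e-05, adjusted p = 0.184 with an estimated correlation), with Fasn at 114 ± 39.6 TPM against 51.5 ± 13.7 TPM. Adipose genes were positive in 11 of 11 with a median of 0.82 (camera adjusted p = 2.20e-05, adjusted p = 0.839 with an estimated correlation). This direction turned without wild type CD library 2 (0.615), and the call was lost without knockout VOFD library 2 (0.398). The median was 1.67 without wild type CD library 1, 0.21 without wild type CD library 2, 1.38 without knockout VOFD library 1 and 0.39 without knockout VOFD library 2. Cholesterol biosynthesis genes had a median of 0.22 (camera adjusted p = 0.0788; 1.34e-04 without wild type CD library 2, 0.0290 without knockout CD library 2 and 0.00712 without knockout VOFD library 2). Luteal genes had one of -0.10 (camera adjusted p = 0.148; 0.0333 without wild type CD library 1 and 0.0295 without knockout CD library 1). Of 28 lists, 9 passed camera with the preset correlation, 5 higher and 4 lower. With an estimated correlation 0 passed and 3 had an unadjusted p under 0.05, and by directional fry 0 passed and 3 had one. By mixed fry the lowest adjusted p was 0.611, for immediate early genes.

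Infertile ovaries, all knockout on the CD diet, differed from the 4 fertile ones of both other groups in 3 luteal genes, 3 cholesterol synthesis genes and a chemokine gene. Ptgfr fell to 4.17 ± 1.73 TPM (n = 3) from 179 ± 61.2 TPM (n = 4), a log2 fold change of -5.11 (SE 0.28, limma BH adjusted p = 9.79e-05). Akr1c18 fell to 3.65 ± 3.59 TPM from 282 ± 214 TPM (log2 fold change -5.92, SE 0.56, adjusted p = 0.00486). Sfrp4 (ENSMUSG00000021319.7, chromosome 13, 19623104 to 19632994) fell to 37.3 ± 30.2 TPM from 686 ± 270 TPM (log2 fold change -4.65, SE 0.68, adjusted p = 0.0328). Ccl8, a monocyte chemokine gene (ENSMUSG00000009185.2, chromosome 11, 82115185 to 82116799), rose to 77.0 ± 30.9 TPM from 13.6 ± 0.663 TPM (log2 fold change 2.33, SE 0.26, adjusted p = 0.0111). Msmo1 fell to 60.3 ± 11.1 TPM from 156 ± 22.6 TPM (-1.36, adjusted p = 0.0190), Idi1 to 16.3 ± 4.78 TPM from 54.3 ± 11 TPM (-1.69, adjusted p = 0.0218) and the lanosterol demethylase gene Cyp51 to 14.3 ± 1.98 TPM from 38.3 ± 7.78 TPM (-1.34, adjusted p = 0.0274).

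**Figure D1:**
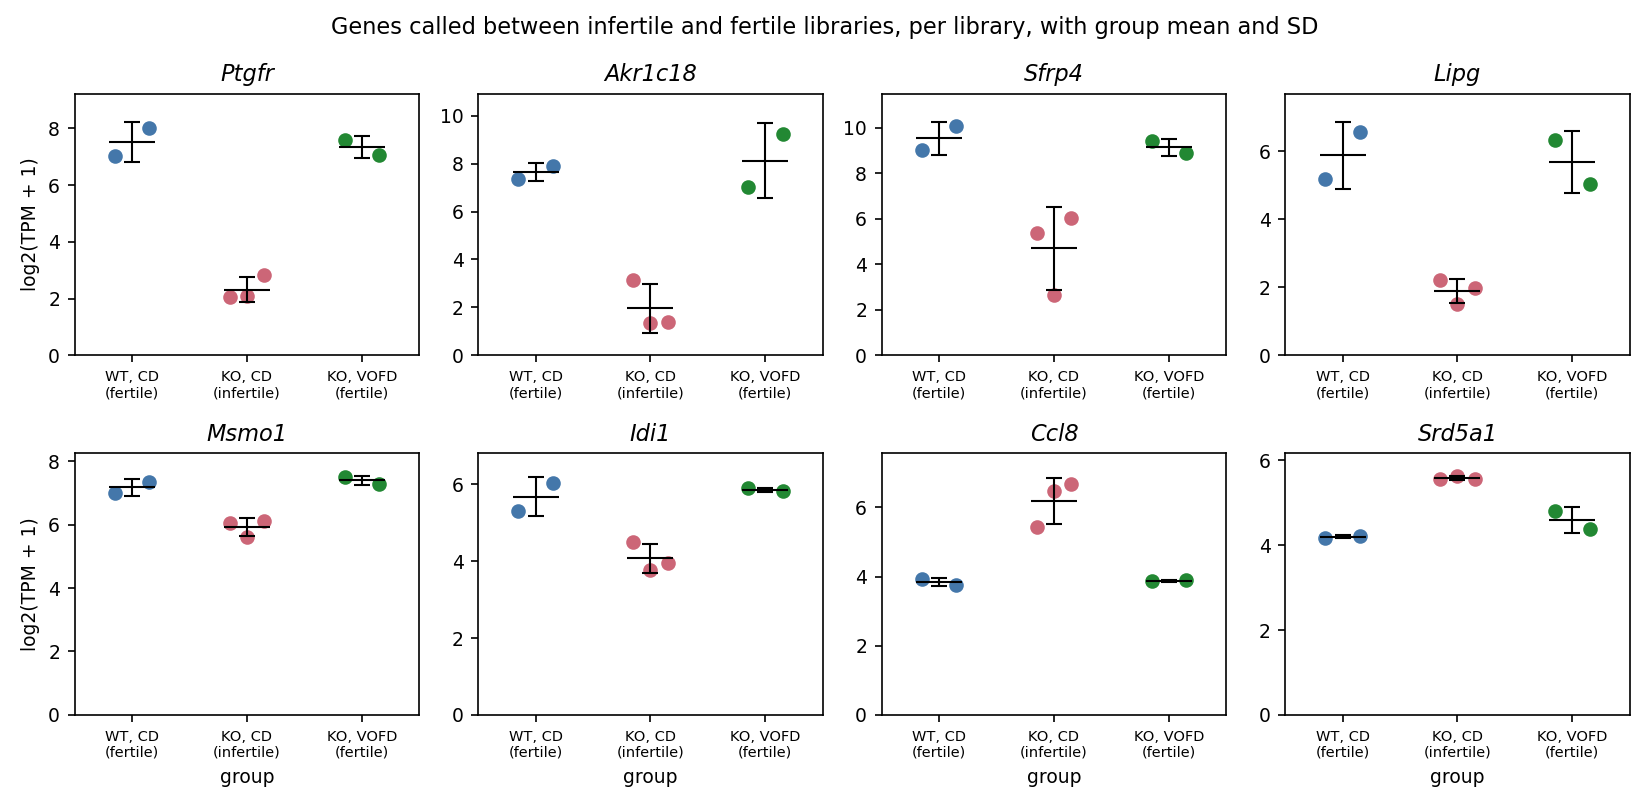
Log2(TPM + 1) of 8 genes called between infertile and fertile ovaries, with 1 point per library, a bar for the group mean and whiskers for the SD of each of the 3 groups. Ptgfr was at a mean of 4.17 TPM in knockout CD and 179 TPM over the fertile libraries, and no infertile library overlapped a fertile one in these genes. The naming rule required this of all but Msmo1 and Idi1, which were named from a list.

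Other named genes that fell in the infertile libraries were Lipg (log2 fold change -3.89, adjusted p = 0.00548), Tnfrsf9 (-3.53, adjusted p = 0.00172), Saa2 (-3.92, adjusted p = 0.0111), the guanine exchange factor gene Plekhg4 (-3.46, adjusted p = 0.0203), the cell adhesion gene Nrcam (-2.95, adjusted p = 0.0271), the semaphorin gene Sema3d (-2.89, adjusted p = 0.0203), Cryba4 (-2.70, adjusted p = 0.0274) and the granulosa cell marker Kctd14 (-0.88, adjusted p = 0.0203). The potassium channel gene Kcnt1 rose to 21.7 ± 1.2 TPM from 5.66 ± 1.77 TPM (1.80, adjusted p = 0.0149), and Srd5a1 to 46.8 ± 1.70 TPM from 20.4 ± 4.62 TPM (1.18, adjusted p = 0.0328). The alpha globin gene Hba-a1 rose to 288 ± 102 TPM from 85.8 ± 20.8 TPM (1.71, adjusted p = 0.0435), and Cd24a, a surface glycoprotein gene, to 57.0 ± 10.4 TPM from 25.7 ± 4.09 TPM (1.12, adjusted p = 0.0497). In total 38 genes passed, 9 higher and 29 lower, with 2389 at an unadjusted p under 0.05. With median-of-ratios scaling 65 passed, 13 higher and 52 lower.

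The count of 38 was 15 without wild type CD library 1, 17 without wild type CD library 2, 665 without knockout CD library 1, 15 without knockout CD library 2 and 19 without knockout VOFD library 1. The balance of 9 higher and 29 lower also rested on single libraries. Without knockout CD library 1, 473 were higher and 192 lower, without wild type CD library 2 the numbers were 8 and 9, without knockout CD library 2 they were 6 and 9, without knockout CD library 3 they were 14 and 18, and without knockout VOFD library 1 they were 8 and 11. Of 19 named and list genes past the threshold, 10 lost their call without wild type CD library 1, 10 without wild type CD library 2, 0 without knockout CD library 1, 14 without knockout CD library 2, 8 without knockout CD library 3, 10 without knockout VOFD library 1 and 7 without knockout VOFD library 2. Their adjusted p then lay between 0.0505 and 0.137. Ptgfr, Akr1c18, Lipg and Tnfrsf9 kept their call in all 7 of these fits. Sfrp4 lost it without wild type CD library 1 (0.137) or 2 (0.0842) and knockout VOFD library 1 (0.0858) or 2 (0.0590). Ccl8 lost it without wild type CD library 1 (0.0581) or knockout CD library 2 (0.0575), and Msmo1 without wild type CD library 2 (0.0610), knockout CD library 2 (0.0575) or knockout VOFD library 1 (0.0558). Idi1 and Cyp51 lost it without wild type CD library 2 (0.0691 and 0.0842), knockout CD library 2 (0.0773 and 0.102) or 3 (0.0615 and 0.0570) and knockout VOFD library 1 (0.0745 and 0.0893) or 2 (0.0590 and 0.0676).

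Over the cholesterol biosynthesis list, 22 of 24 members were negative in infertile against fertile with a median of -0.74, and 3 fell over all genes tested and 12 adjusted over the list alone (camera adjusted p = 5.74e-21, adjusted p = 0.473 with an estimated correlation). The luteal list had a median of -0.67, with 3 members lower over all genes and 6 adjusted over the list alone (camera adjusted p = 3.47e-10, adjusted p = 0.473 with an estimated correlation). Over all genes tested the cholesterol list had 8 lower members without knockout CD library 1, 1 without knockout CD library 3, and 0 without wild type CD library 2, knockout CD library 2 or knockout VOFD library 1. The luteal list had 9 lower without knockout CD library 1, and 10 adjusted over the list alone, with a median of -1.11. Steroidogenesis genes did not pass camera (adjusted p = 0.103; 0.00981 without knockout CD library 1 and 0.0443 without knockout VOFD library 1), with Akr1c18 lower and Srd5a1 higher over all genes. Cyp11a1, Star and Hsd3b1, which carry cholesterol to progesterone and were chosen after their values were seen, had overlapping groups, with Hsd3b1 between 3856 and 5326 TPM in knockout CD and between 4196 and 5183 TPM in the fertile libraries. Erythroid genes were positive in 5 of 5 with a median of 1.63, 1 past over all genes and 5 adjusted over the list alone (camera adjusted p = 1.44e-06, adjusted p = 0.558 with an estimated correlation). The adipose list had a median of 1.61, with 0 past over all genes and 9 adjusted over the list alone (camera adjusted p = 1.25e-04, adjusted p = 0.608 with an estimated correlation; 0.0567 without knockout CD library 1). Adjusted over the list alone, the adipose count was 1 without knockout CD library 1, 0 without knockout CD library 2, and 5 without knockout VOFD library 1.

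Proliferation genes were positive in 19 of 19 with a median of 0.50, 0 past over all genes and 6 adjusted over the list alone (camera adjusted p = 2.50e-05, adjusted p = 0.608 with an estimated correlation). That count was 16 without knockout CD library 1, 2 without wild type CD library 1, knockout CD library 2, knockout CD library 3 or knockout VOFD library 2, and 3 without wild type CD library 2 or knockout VOFD library 1, and the median was 0.32 without knockout CD library 3. Neutrophil and mast cell genes were positive in 9 of 9 with a median of 1.07, 0 past over all genes and 6 adjusted over the list alone (camera adjusted p = 7.45e-04, adjusted p = 0.608 with an estimated correlation; 0.224 without knockout CD library 2). Their count of 6 was 0 without knockout CD library 2, 3 without either wild type CD library and 2 without knockout VOFD library 1, and the median was 0.66 without knockout CD library 2. Lymphocyte genes had a median of 0.49 (camera adjusted p = 0.0101, adjusted p = 0.608 with an estimated correlation; 0.0869 without knockout CD library 2), with Jchain, a plasma cell gene, at 37.2 ± 22.4 TPM against 6.15 ± 1.83 TPM (adjusted p = 0.0802). Oocyte genes were negative in 31 of 33 with a median of -0.36 and 0 past either threshold (camera adjusted p = 1.80e-08, adjusted p = 0.658 with an estimated correlation; 0.127 without knockout CD library 1). Their median was 0.04 without knockout CD library 1 and -0.65 without knockout CD library 2, with 1 member higher and 1 lower, in the same order, adjusted over the list alone. Mitochondrially encoded genes were negative in 13 of 13 with a median of -0.25 (camera adjusted p = 1.73e-06, adjusted p = 0.608 with an estimated correlation; 0.0809 without knockout CD library 3, 0.104 with the replicate block). Their median was -0.41 without knockout CD library 1 and -0.11 without knockout CD library 3. Of 28 lists, 11 passed camera with the preset correlation, 6 higher and 5 lower. With an estimated correlation 0 passed and 2 had an unadjusted p under 0.05, and by directional fry 0 passed and 6 had one. By mixed fry the luteal (adjusted p = 2.4e-04), steroidogenesis (8.17e-04) and cholesterol lists (0.0124) were among those that passed. The oocyte (0.453) and mitochondrially encoded lists (0.25) were among those that did not. Akr1c18 stands in both the luteal and the steroidogenesis list.

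**Figure D2:**
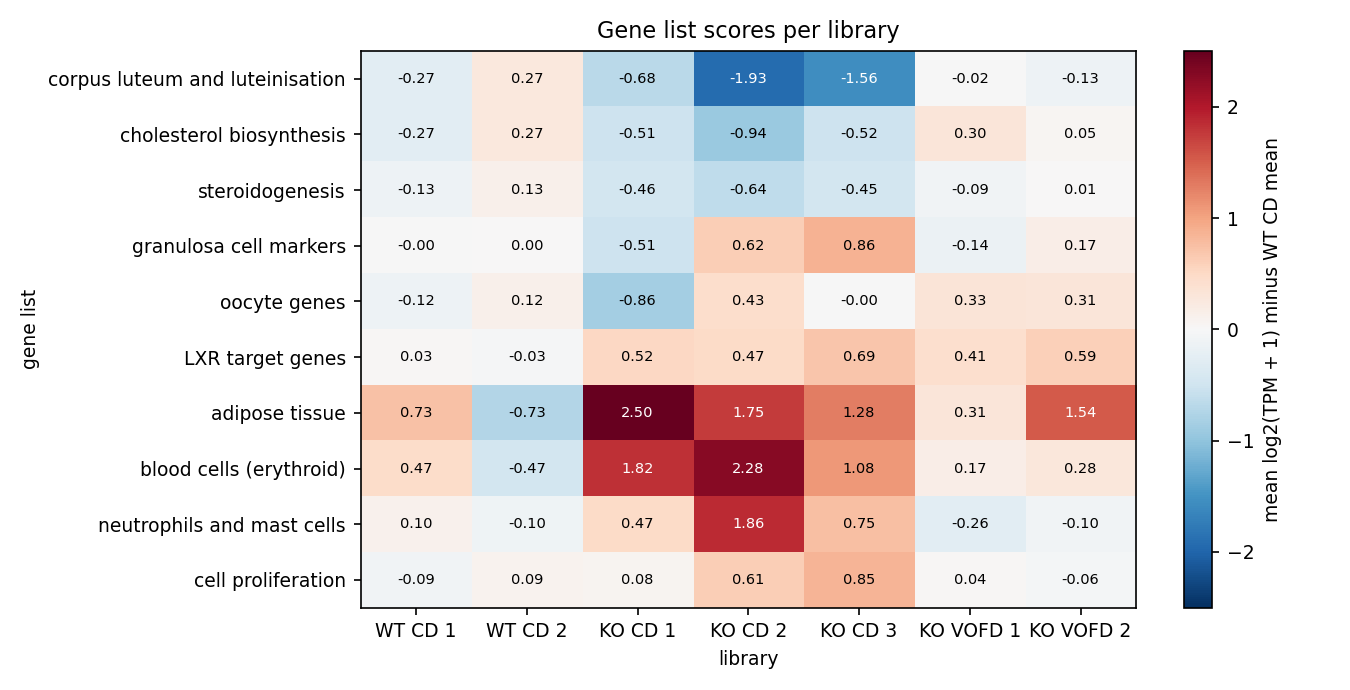
Score of 10 gene lists in each of the 7 libraries, as the mean log2(TPM + 1) of the members minus the mean of the 2 wild type CD libraries, with colour for the difference. The 3 knockout CD libraries had luteal scores of 6.94, 5.69 and 6.06 before that subtraction, against 7.36 to 7.89 in the fertile libraries, and erythroid scores of 6.91 to 8.10 against 5.35 to 6.29.

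Several called genes were processed pseudogenes, copies of other transcripts whose reads cannot be told from those of the source gene with certainty. Gm12191 (chromosome 11, 49678710 to 49679057) matched the ribosomal protein gene Rpl30 with 99.71% identity over 348 of its 348 bases. It was at 969, 1344 and 817 TPM in knockout CD, at 0.0130 and 0 TPM in wild type CD and at 2.02 and 0.000164 TPM in knockout VOFD. Rpl30 was at 1845 TPM in infertile against 3106 TPM in fertile libraries, lower by a mean difference of -1260 TPM (SE 230), while Gm12191 was higher by 1043 TPM. Gm45315 matched Hmgb1 with 98.8% identity, was listed at 0 in both wild type CD libraries and was at 242 and 127 TPM in knockout VOFD, where Hmgb1 differed by -334 TPM (SE 30.2). Gm9855 matched Tdg with 99.25% identity, Gm6969 matched Cox7a2l with 97.66%, Gm3226 matched the tubulin gene Tuba1b with 98.67%, Gm21596 matched Hmgb1 with 99.47%, and Gm48836 matched the olfactory receptor gene Olfr46 with 96.8%. These calls are uncertain for that reason. TPM is divided by length, and the lengths of the matching genes were not compared. Reads placed on a short copy can thus add more TPM to it than a longer source gene loses. Cox7a2l differed by -22.7 TPM (SE 28.0) in knockout CD against wild type CD, where Gm6969 was higher by 202 TPM. Olfr46 was at 0.461 TPM in wild type CD.

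**Figure D3:**
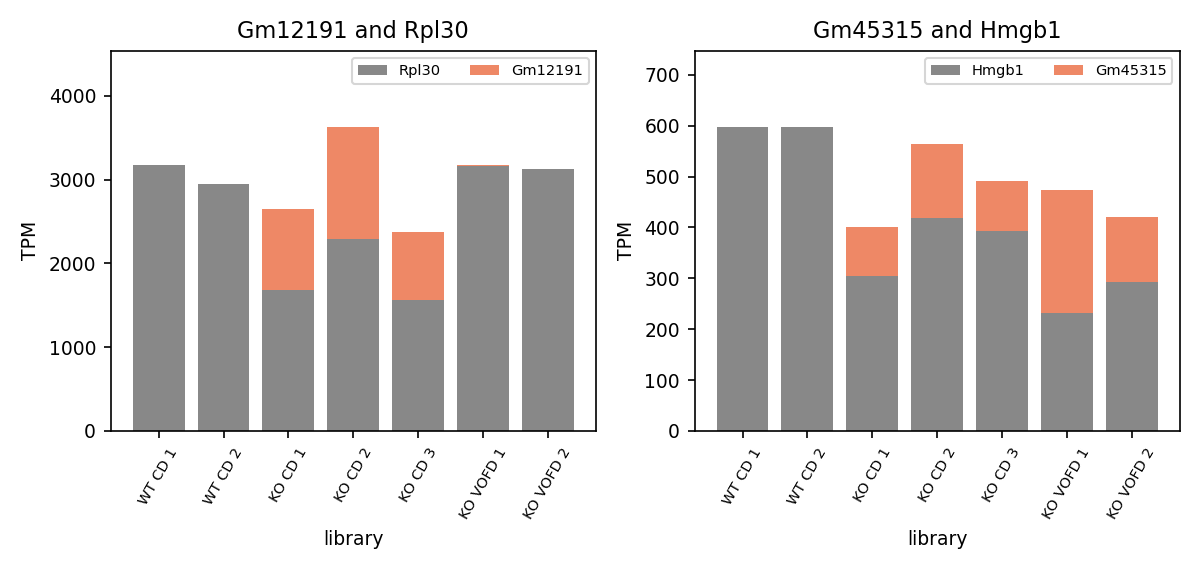
TPM of the pseudogenes Gm12191 and Gm45315 stacked on their best matching genes Rpl30 and Hmgb1, with 1 bar per library from 0. Gm12191 reached 817 to 1344 TPM in the 3 knockout CD libraries, in which Rpl30 was at a mean of 1845 TPM, and Gm45315 was listed at 0 in both wild type CD libraries.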

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

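The tests of scaling, dilution, single libraries (luteal genes), LXR targets, shared reads, variants and the abundance of all-or-none genes were chosen only after the results they concern were seen, and those of single libraries (cholesterol genes), the number of all-or-none genes and other splits of the libraries were chosen before.

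Ptgfr, Akr1c18 and Sfrp4, which are expressed by luteal cells, were lower in the 3 infertile libraries. A difference in scaling between libraries did not account for it, since the median log2 fold change of the 3 genes was -5.2594 with median-of-ratios scaling. With 1 library left out the direction could not turn, since the infertile and fertile values of these genes did not overlap. The value nearest 0 over the 3 genes and the 7 fits that left out 1 library was -3.6239. The fall thus stayed large without any 1 library, although the Sfrp4 call was lost in 4 of these fits. Dilution of ovarian RNA by adipose tissue or blood was argued against as the whole cause, since 66 granulosa, theca and oocyte list members had a median of -0.2223 (SD 0.5229) against -5.1072 for the 3 genes. A lower share of luteal cells, or less expression in each luteal cell, may lie behind it and stays open, since bulk TPM cannot tell these apart and the stage of the oestrous cycle is not given in the sources used here.

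Cholesterol synthesis genes such as Msmo1, Idi1 and Cyp51 were lower in the infertile libraries. The list median was -0.8883 with median-of-ratios scaling, and the value nearest 0 with 1 library left out was -0.5997, so neither scaling nor a single library gave the direction. Msmo1 lost its call in 3 of the 7 fits that left out 1 library, and Idi1 and Cyp51 theirs in 5 each. Over the 16 alternatives the log2 fold change lay between -1.63 and -1.20 for Msmo1 and between -1.95 and -1.54 for Idi1. For Cyp51 it lay between -1.55 and -1.23. Lost calls therefore cannot tell the weight of a single library from the smaller number of libraries. The list had a camera adjusted p of 5.74e-21 and adjusted p = 0.473 with an estimated correlation. Repression of SREBP2 by sterols together with LXR activation is a candidate explanation that stays open, since the LXR target list had a camera adjusted p of 0.5375 in infertile against fertile (adjusted p = 0.952 with an estimated correlation). That list was higher both in knockout CD and in fertile knockout VOFD against wild type CD (camera adjusted p = 0.0271 and 2.20e-05, adjusted p = 0.473 and 0.184 with an estimated correlation). The cholesterol medians there were -0.60 and 0.22, so higher LXR targets did not always go with lower cholesterol genes. The adipose list was also higher in both comparisons (medians 2.02 and 0.82). LXR targets of ovarian cells therefore cannot be told from those of adipose tissue here. The medians of -0.60 on 1 diet and 0.84 between knockout VOFD and knockout CD both use the same knockout CD libraries. Neither list result passed camera with an estimated correlation (adjusted p = 0.473 and 0.682). These medians therefore cannot decide between genotype, diet and a shift in those libraries. The 0.22 ranged from -0.10 without wild type CD library 1 to 0.47 without wild type CD library 2. Infertility cannot be separated from the knockout on the CD diet.

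Several called pseudogenes, among them Gm12191 and Gm45315, were present in some groups and near 0 in others. Reads shared with the best matching gene may account for Gm12191 and Gm45315. Rpl30 and Hmgb1 were lower by at least 0.5 of the gain by more than 2 SE. Cox7a2l missed that bound for Gm6969 by more than 2 SE. The 2 of 3 cases that met the bound left shared reads open for the 8 pseudogenes with a match as a set. Tdg lay too near the bound for Gm9855. Olfr46 was at 0.461 TPM in wild type CD, against the 11.8 TPM that Gm48836 gained in knockout CD. Shared reads stay open for Gm6969 and Gm48836 too, since TPM is divided by length. A short copy can gain more TPM than a longer source gene loses. Only the best matching protein coding gene of each was compared. For genes present in all libraries of a group and near 0 in the rest, 21 of 21 splits gave as many as wild type CD, 15 of 35 as many as knockout CD and 18 of 21 as many as knockout VOFD (real counts 2, 3 and 3, highest others 9, 5 and 9), so chance could account for their number. That number says nothing of single genes, and Gm45315 and Gm16232 passed over all genes tested (BH adjusted p = 3.61e-05 in knockout CD against wild type CD and 0.00565 in knockout VOFD against knockout CD). That 1 of 21 splits into 2 and 5 libraries had an all-or-none gene as abundant as Gm45315 decides nothing, since the bar was the level of that gene. A variant fixed with the genotype was argued against for 2 of the 9 called pseudogenes, Gm12191 and Gm16232, which differed between the knockout groups. It stays open for those lower in wild type CD alone, such as Gm45315, listed at 0 there, and Gm6969, at 3.14 ± 1.09 TPM there. Pseudogenes made up 19.15% of 47 called genes against 6.128% of those tested (Fisher's exact test, one-sided, p = 0.001938), which cannot tell a strain or colony variant from shared reads, and no biological explanation was tested.

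Of the 35 splits of the 7 libraries into 3 and 4, 1 gave as many genes as infertile against fertile, which is the real split. Chance is therefore unlikely for this count, but 35 splits are too few to exclude it. The real value was 38 and the highest of the other splits was 10.

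Among 145 values tested in the 4 fertile libraries, 6 had 1 library far from the other 3 (Dixon's test at its 95% critical value), where chance gives about 1 in 20, or 7.25 of them, so these 6 are no more than chance gives. The fertile group pools wild type CD and knockout VOFD. Knockout VOFD library 2 stood apart in Cxcl10, an interferon-induced chemokine gene (2.53 against 2 to 2.07 in log2(TPM + 1)), in Igfbp5, an insulin-like growth factor binding protein gene (8.3 against 7.82 to 7.86), and in the oviduct epithelium score (3.61 against 2.34 to 2.48). Wild type CD library 2 stood apart in the smooth muscle gene Lmod1 (2.65 against 2.29 to 2.34) and the globin gene Hba-a2 (7.27 against 7.92 to 8), and wild type CD library 1 in the oxidative stress response score (6.46 against 6.58 to 6.61).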

How the results depend on the processing

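Library quality weights and crossed replicate numbers were chosen only after the results were seen, and the other alternatives were planned. The genes past the threshold numbered 17 in knockout CD against wild type CD, 7 in knockout VOFD against knockout CD, 2 in knockout VOFD against wild type CD, 38 in infertile against fertile, and 5 changed back on the VOFD diet. A pseudocount of 0.1 gave 4 in knockout VOFD against knockout CD and 7 in knockout VOFD against wild type CD. With no filter the counts were 3 in knockout CD against wild type CD, 5 in knockout VOFD against wild type CD, 4 in infertile against fertile and 1 changed back. Median-of-ratios scaling gave 65 and quantile normalisation 59 in infertile against fertile. With no variance trend 5 genes passed in knockout VOFD against wild type CD. The fit with other samples gave 4 in knockout VOFD against knockout CD, 21 in knockout VOFD against wild type CD and 3 changed back. The replicate number as a block gave 27 in knockout CD against wild type CD, 12 in knockout VOFD against wild type CD and 15 in infertile against fertile, and the block with crossed numbers gave 11 in knockout VOFD against wild type CD. Library quality weights gave 48, 179, 15, 299 and 37 in the order above, with 87 higher and 92 lower in knockout VOFD against knockout CD and 160 higher and 139 lower in infertile against fertile. The causes were not tested.

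With 1 library left out, the counts ranged from 4 without wild type CD library 2 to 174 without knockout CD library 1 in knockout CD against wild type CD. In knockout VOFD against knockout CD they ranged from 3 without knockout CD library 2 or knockout VOFD library 1 to 104 without knockout CD library 1. In knockout VOFD against wild type CD the range was 2 to 14, the latter without knockout CD library 3. In infertile against fertile it was 15, without wild type CD library 1 or knockout CD library 2, to 665, without knockout CD library 1. Genes changed back numbered 2 without wild type CD library 2 or knockout CD library 2, and 80 without knockout CD library 1. Without knockout CD library 1 all 17, 7, 2, 38 and 5 genes kept their calls. Where a group was left with 1 library, that library is assumed to vary like the other groups.

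No named gene that passed the threshold changed direction under any alternative. With a library left out, or another pseudocount, filter or variance trend, none could have done so, since the groups of each such gene did not overlap. Calls were kept in 96 of 144 cases in knockout CD against wild type CD, 38 of 64 in knockout VOFD against knockout CD and 203 of 304 in infertile against fertile. Ptgfr in knockout CD against wild type CD lost its call with no filter alone (adjusted p = 0.0506). Among values past the threshold under neither setting, direction differed in 31 of 6858 for named genes and 81 of 591 for gene lists. Median-of-ratios scaling moved the median fold change of all genes in knockout CD against wild type CD from 0.19 to -0.0045, and in infertile against fertile from 0.15 to 0.0001.

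With an estimated correlation 0 of 28 gene lists passed by camera in each of the 4 comparisons, where 1, 2, 3 and 2 had an unadjusted p under 0.05, and by directional fry 0 passed. Mixed fry passed some lists in the 3 comparisons with knockout CD. With 1 library left out, 10 to 18 lists passed in knockout CD against wild type CD (10 without knockout CD library 2), 10 to 12 in knockout VOFD against knockout CD, 9 to 11 in knockout VOFD against wild type CD and 8 to 14 in infertile against fertile. Cholesterol, luteal and erythroid calls were kept in all 7 such fits in the 3 comparisons with knockout CD. Lists that passed with the replicate block and not without it were smooth muscle in knockout CD against wild type CD (0.00489) and in infertile against fertile (1.96e-04), the unfolded protein response in these and in knockout VOFD against knockout CD (0.0419, 0.0117 and 0.0108), and interferon-stimulated genes (0.0356) and oviduct epithelium (0.00239) in the latter. All of these but the interferon list also passed without knockout CD library 3, the only library with its replicate number (0.00622, 1.61e-04, 0.0410, 0.0179, 0.0218 and 0.00386 in that order), and the interferon list did without knockout CD library 2 (0.00536). Smooth muscle in infertile against fertile passed without wild type CD library 2 (0.0319), the unfolded protein response in knockout CD against wild type CD without wild type CD library 1 (0.0460), and the oviduct list without knockout VOFD library 1 (1.01e-05). Adjusted over the list alone, median-of-ratios scaling and quantile normalisation gave 14 and 14 cholesterol genes in knockout CD against wild type CD in place of 9, 0 and 0 lymphocyte genes in place of 2, and in infertile against fertile 5 and 3 adipose genes in place of 9 and 1 and 1 neutrophil genes in place of 6. Direction was opposite for 7 list results, given here with the range of adjusted p over the 7 fits. In knockout VOFD against wild type CD these were the adipose list (adjusted p = 0.615, range 4.77e-21 to 0.615) and the erythroid list (0.0129, range 9.43e-05 to 0.914) without wild type CD library 2. The surface epithelium list turned without knockout VOFD library 1 (0.0228, range 4.65e-05 to 0.412) and the oviduct list without knockout VOFD library 2 (0.653, range 9.38e-10 to 0.653). The others were the oocyte list in knockout CD against wild type CD without knockout CD library 1 (0.796, range 3.80e-15 to 0.796), and the extracellular matrix list. It turned without knockout CD library 2 in that comparison (0.0379, range 0.0199 to 0.911) and without knockout CD library 1 in infertile against fertile (0.0457, range 0.0161 to 0.992). The causes were not tested. The depth of the libraries is unknown, so its limit on low genes could not be computed.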

Other observations

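Every test in this part was planned, and the genes Cyp11a1, Star and Foxj1 were chosen only after their values were seen. Ovulation and cumulus expansion genes had medians of -0.23 in knockout CD and -0.30 in knockout VOFD against wild type CD (camera adjusted p = 0.0278 and 8.47e-04, adjusted p = 0.678 and 0.839 with an estimated correlation). The knockout CD call was lost without wild type CD library 1 (0.0553), knockout CD library 2 (0.647) or knockout CD library 3 (0.212), with median-of-ratios scaling (0.161) and with the replicate number as a block (0.234). That median was 0.10 without knockout CD library 2, -0.01 without wild type CD library 2, -0.51 without knockout CD library 1 and -0.10 without knockout CD library 3, and the -0.30 was -0.04 without wild type CD library 2 and -0.10 without knockout VOFD library 2. Ovarian surface epithelium genes had medians of -0.26 in knockout CD against wild type CD, 0.22 in knockout VOFD against knockout CD and -0.27 in infertile against fertile (camera adjusted p = 0.00145, 0.0101 and 0.00157, adjusted p = 0.649, 0.710 and 0.608 with an estimated correlation). These calls were lost without wild type CD library 1 (0.208), without knockout CD library 2 (0.121), knockout CD library 3 (0.113) or knockout VOFD library 2 (0.952), and without knockout CD library 2 (0.0521), in the same order, and the middle one with the replicate block (0.113). The -0.26 was -0.41 without knockout CD library 1. The 0.22 was 0.39 without knockout CD library 1, 0.08 without knockout CD library 2, 0.37 without knockout VOFD library 1 and -0.02 without knockout VOFD library 2. The -0.27 was -0.18 without knockout CD library 2 and -0.17 without knockout VOFD library 2. Smooth muscle and pericyte genes had a median of -0.51 in knockout VOFD against knockout CD (camera adjusted p = 0.0140, adjusted p = 0.710 with an estimated correlation; 0.529 without knockout CD library 1 and 0.0503 without knockout VOFD library 1). None of these lists had a member past the threshold over all genes or adjusted over the list alone in these comparisons with all libraries. Adjusted over the list alone, 2 ovulation and 2 surface epithelium genes fell without knockout CD library 1 in knockout CD against wild type CD, and 2 surface epithelium genes rose in knockout VOFD against knockout CD and 2 fell in infertile against fertile without it, the last 2 also over all genes. In knockout VOFD against knockout CD 4 smooth muscle genes fell without knockout CD library 2 and 3 without knockout CD library 3.

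Immediate early genes had medians of -0.16 in knockout CD against wild type CD and -0.39 in knockout VOFD against knockout CD (camera adjusted p = 0.00233 and 0.00314, adjusted p = 0.473 and 0.697 with an estimated correlation). The first call was lost without knockout CD library 3 (0.230) and with the replicate block (0.260), and its median was -0.24 without wild type CD library 1, -0.01 without wild type CD library 2, -0.28 without knockout CD library 2 and -0.02 without knockout CD library 3. The second was lost without knockout CD library 1 (0.0516), knockout CD library 2 (0.0675) or knockout VOFD library 2 (0.0680). Mitochondrially encoded genes had a median of 0.29 and lymphocyte genes one of -0.38 in knockout VOFD against knockout CD (camera adjusted p = 1.42e-05 and 0.00314, adjusted p = 0.697 for both with an estimated correlation), and the first call was lost without knockout CD library 3 (0.0994, median 0.12) and with the replicate block (0.151). The lymphocyte median was -0.57 without knockout CD library 1 and -0.59 without knockout VOFD library 1. Macrophage genes had a median of 0.46 in infertile against fertile, with 2 of 19 past when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0428, adjusted p = 0.881 with an estimated correlation). That call was lost without wild type CD library 1 (0.0620) or 2 (0.0783) and without knockout CD library 2 (0.238) or 3 (0.113), and the count of 2 was 12 higher and 1 lower without knockout CD library 1 and 0 in the other fits except without knockout VOFD library 1. The median was 0.27 without knockout CD library 3, and the call was also lost with the replicate block (0.124).

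In knockout VOFD against wild type CD, oocyte genes had a median of 0.32, lipid storage genes 0.33 and interferon-stimulated genes -0.15, each with a camera adjusted p of 0.00238 (adjusted p = 0.839, 0.184 and 0.839 with an estimated correlation). The lipid call was lost without wild type CD library 2 (0.349) and knockout VOFD library 2 (0.0883, median 0.21). The oocyte median was 0.21 without wild type CD library 1, and the interferon median -0.27 without wild type CD library 1 and -0.04 without wild type CD library 2. Oviduct epithelium genes had a median of 0.54 (camera adjusted p = 0.0204, adjusted p = 0.839 with an estimated correlation; 0.427 without wild type CD library 2, and the opposite direction with 0.653 without knockout VOFD library 2). Their median was 0.90 without knockout VOFD library 1 and 0.10 without knockout VOFD library 2. Neutrophil and mast cell genes had a median of -0.17 (camera adjusted p = 0.0465, adjusted p = 0.839 with an estimated correlation; 0.766 without wild type CD library 1, 0.0619 without knockout CD library 1, 0.181 without knockout VOFD library 1 and 0.299 with median-of-ratios scaling). Their median was -0.09 without wild type CD library 1, -0.35 without wild type CD library 2 and -0.30 without knockout VOFD library 2.

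The remaining lists did not pass camera with the preset correlation in any of the 4 comparisons, although the unfolded protein response did in 3 of them with the replicate block or without knockout CD library 3 (0.0410, 0.0218 and 0.0179), and in knockout CD against wild type CD without wild type CD library 1 (0.0460). Granulosa cell markers had medians between -0.46 and 0.53 (camera adjusted p 0.490 to 0.902), with 1 member, Kctd14, lower over all genes in infertile against fertile and 13 higher adjusted over the list alone without knockout CD library 1, and theca and interstitial cell markers between -0.13 and 0.34 (0.288 to 0.907). Without knockout CD library 1 the granulosa list passed in the 3 comparisons with knockout CD (8.11e-04, 8.16e-05 and 3.51e-04) and the theca list in knockout VOFD against wild type CD (0.0295), where the granulosa list passed without knockout VOFD library 2 (0.0337). The ranges of camera adjusted p were 0.497 to 0.880 for inflammatory cytokines, 0.385 to 0.907 for extracellular matrix, 0.123 to 0.506 for both endothelium and apoptosis and follicle atresia, 0.148 to 0.891 for the unfolded protein response and ATF4, 0.679 to 0.921 for oxidative stress response, and 0.235 to 0.971 for gonadotropin, prolactin and oestrogen receptors and signalling. The endothelium list passed without knockout CD library 1 in knockout CD against wild type CD (0.00907) and infertile against fertile (0.0138), and so did the receptor list in the former (0.0394). The extracellular matrix list passed in knockout CD against wild type CD without knockout CD library 1 (0.0199) or 2 (0.0379), in knockout VOFD against knockout CD without knockout CD library 2 (0.00693) and in infertile against fertile without knockout CD library 1 (0.0457) or 2 (0.0161).

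Some genes differed between libraries of 1 group. The cilia gene Foxj1 was at 7.16 TPM in knockout CD library 3 and 7.02 TPM in knockout VOFD library 2, against 0.289 to 1.14 TPM in the other 5 libraries, and the same 2 libraries had oviduct epithelium scores of 3.90 and 3.61 against 2.34 to 2.66. Cyp11a1, which starts steroid synthesis from cholesterol, was at 2481 TPM in knockout CD library 1 and at 250 and 602 TPM in knockout CD libraries 2 and 3. Star, the mitochondrial cholesterol carrier gene, was at 603 TPM in knockout CD library 1 and at 93.7 and 61.9 TPM in the others of that group.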
